A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

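Gene expression was measured on one-colour DNA microarrays in the yeast Saccharomyces cerevisiae strain BY4741, a common laboratory haploid. The cells carried either the empty plasmid pYES2, a vector with a galactose-inducible promoter, or the same plasmid with an insert that the labels call rPLC, which the series title describes as overexpression of phospholipase C. The labels' protocols state that cells grew in synthetic minimal medium without uracil and were induced with 2% galactose for 2 h or 5 h. There was 1 array for each of the 4 combinations of plasmid and time, and all 4 arrays lay on 1 slide in 1 scan, so that no slide or scan effect could be tested. The series design text calls the 2 h and 5 h inductions biological replicates. Whether each array came from a separate culture is not stated beyond that, so the limma p-values of genes measure only the spread between these arrays.

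The deposited scanner files hold the intensity of each spot on a linear scale, written by Agilent Feature Extraction 10.5.1.1 per the file headers. The processed intensity in these files was background-subtracted and detrended on each array but not normalized between arrays, per the file headers. The deposited series matrix holds log2 values, and the steps that gave them are not given in the sources used here. Set against the scanner values, its columns matched log2 of the processed signal with r of at least 0.991 across probes. Each column had a 75th percentile of 0, so its scale was log2 and each array was centred on that percentile, with genes not centred. The matrix medians were -1.39 for vector 2 h, -1.3 for vector 5 h, -1.41 for rPLC 2 h and -1.38 for rPLC 5 h. With 1 colour on each array no ratio direction was involved, and none of scale, centring or direction stays unknown.

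Each array had 15208 spots that were not controls, for 6256 probes with 1 probe per gene. Of the probes 3560 had 2 spots and 2696 had 3 spots. The 536 control spots and the spots with outlier flags were left out, and saturated spots were kept. The main values were log2 of the processed signal, averaged over the spots of a probe, minus the array's 75th percentile over probes. A probe entered the test if it was well above background on at least 2 of the 4 arrays. It also needed a spot without an outlier flag on each of the 4 arrays, which left 6113 genes. For the folds at 1 time, a gene entered if it was well above background on at least 1 of the 2 arrays. A spot without an outlier flag on both arrays was needed there too. Gene names are those of the array files, and 5756 of the 6256 systematic names matched the gene table of assembly R64, which was used for names alone. No coordinates are given, since the build behind the array design is not given in the sources used here. Where a probe was not well above background on one of the arrays compared, or was saturated on the brighter one, the fold is a bound and is written with "at least", unless the spots of a saturated probe lay over 2-fold apart on the other array. For a dim probe it is taken against the higher of the lowest signal well above background on that array and the probe's own value.

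Plasmid and time were tested together with limma 3.58.1 in R 4.3.3, in an additive model with both factors, eBayes without a trend, and Benjamini-Hochberg adjustment over all genes tested at 0.05. With 4 arrays and 3 coefficients the model had 1 residual degree of freedom, and its residual held any difference in the plasmid effect between the times. Folds at 2 h alone or 5 h alone rest on 1 array per group and have no test. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01. The 38 of 39 lists with at least 5 tested genes were used. They were tested again with an estimated correlation and with limma's fry. Camera sets the genes of a list against all other genes. At the preset correlation its p-values therefore rest on genes as units and do not measure the spread between arrays or cultures. The median fold of each list was also set against 10000 random lists of the same size matched on mean expression, as a description of these arrays.

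The lists covered phospholipid synthesis under inositol-choline control, phosphatidate and triacylglycerol metabolism, phosphoinositides, sphingolipids and ergosterol. Others covered phosphate, zinc, iron, sulfur, arginine, amino acid, nitrogen and nucleotide metabolism, and carbon metabolism from the galactose genes to respiration and peroxisomal fatty acid oxidation. Stress and signalling lists covered the general, heat shock, oxidative, unfolded protein, calcineurin, cell wall, drug efflux and pheromone responses. The remaining lists covered meiosis, cell cycle phases, histones, ribosomes and translation, the proteasome, autophagy, hypoxic cell wall genes, and markers of the strain and plasmid.

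The genes named for each of the 2 contrasts were the 12 highest and 12 lowest that passed, and, since none passed, the 12 with the largest mean fold in each direction. These had to be well above background on all 4 arrays and changed at least 2-fold in the same direction in both pairs of arrays. At each time alone the 5 highest and 5 lowest genes by fold were named, along with 6 members of the phospholipid list, up to 4 members of each other list described, and a set of checks. The groups, models, lists, naming rule and most alternatives were fixed before the data were examined.

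The test and list steps were tested on simulated data before use. In 10 simulated sets of 4 arrays with 6113 genes and 200 changed genes, the limma test called 1.4% of the genes changed by 1 on the log2 scale. It called 16.4% of those changed by 2, 68% of those changed by 3 and 92.2% of those changed by 5, and it called 67 unchanged genes over all sets. Of the unchanged genes 5.12% had an unadjusted p under 0.05. A list of 20 genes shifted by 0.6 was called in 10 of the 10 sets, and 0 of the unshifted lists were called. The simulated genes varied independently of each other, so these list counts do not show how camera behaves on genes that vary together.

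The median processed signal was 2412 on the vector 2 h array, 1813 on vector 5 h, 1435 on rPLC 2 h and 1953 on rPLC 5 h, while the mean net signal of negative controls lay between 34.7 and 38.1. What limits the precision most, the number of arrays, the spots or the scaling, was not tested. The alternatives fixed in advance were quantile normalization, scaling to the median, normexp background correction with an offset of 50, no filter on dim probes, a filter on all 4 arrays and the series matrix values. Further ones were an intensity trend with a robust prior, no block, each array left out in turn, an adjusted p under 0.1 and a 1.5-fold threshold.

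Maps of the spots showed patches of low signal, and 4 alternatives were chosen after seeing the data. The first left out spots in dim patches. There the neighbouring spots within 3 rows and 2 columns lay on median over 0.5 log2 units below their own medians over the 4 arrays. In simulated data this step found 95.3% of the spots of a patch and took 0.0033% of the others. The simulated arrays were noisy copies of the same array, with a single patch of 257 spots shifted by -3 on the log2 scale. Milder or smaller patches, and arrays that differ in expression, were not simulated, so these rates may not hold for the real arrays. The second also kept only the 4457 genes with at least 2 remaining spots on every array lying within 2-fold of each other, and its requirement of at least 2 spots was set after its first results were seen. The third took the median of the spots, and the fourth joined the second with quantile normalization.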

Results

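The transcript levels of 6256 yeast genes were measured on 4 one-colour arrays, 1 each for vector and rPLC cells after 2 h and after 5 h of induction with galactose. The comparison asks how expression of a phospholipase C, an enzyme that cleaves phospholipids into diacylglycerol and a phosphorylated head group, altered the yeast transcriptome. Between 6069 and 6140 of the 6256 probes were well above background on each array. The 75th percentile of the processed signal was 6289 on the vector 2 h array, 4474 on vector 5 h, 3825 on rPLC 2 h and 5080 on rPLC 5 h. Patches of low signal held 201 spots on the vector 2 h array, 26 on vector 5 h, 106 on rPLC 2 h and 784 (5.16% of 15208) on rPLC 5 h. On the same arrays 582, 287, 467 and 951 of the 6256 probes had spots over 2-fold apart. Each group had 1 array, so values at 1 time carry no error, and values over both times carry the standard error (SE) of the limma fit on 4 arrays.

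**Figure D1:**
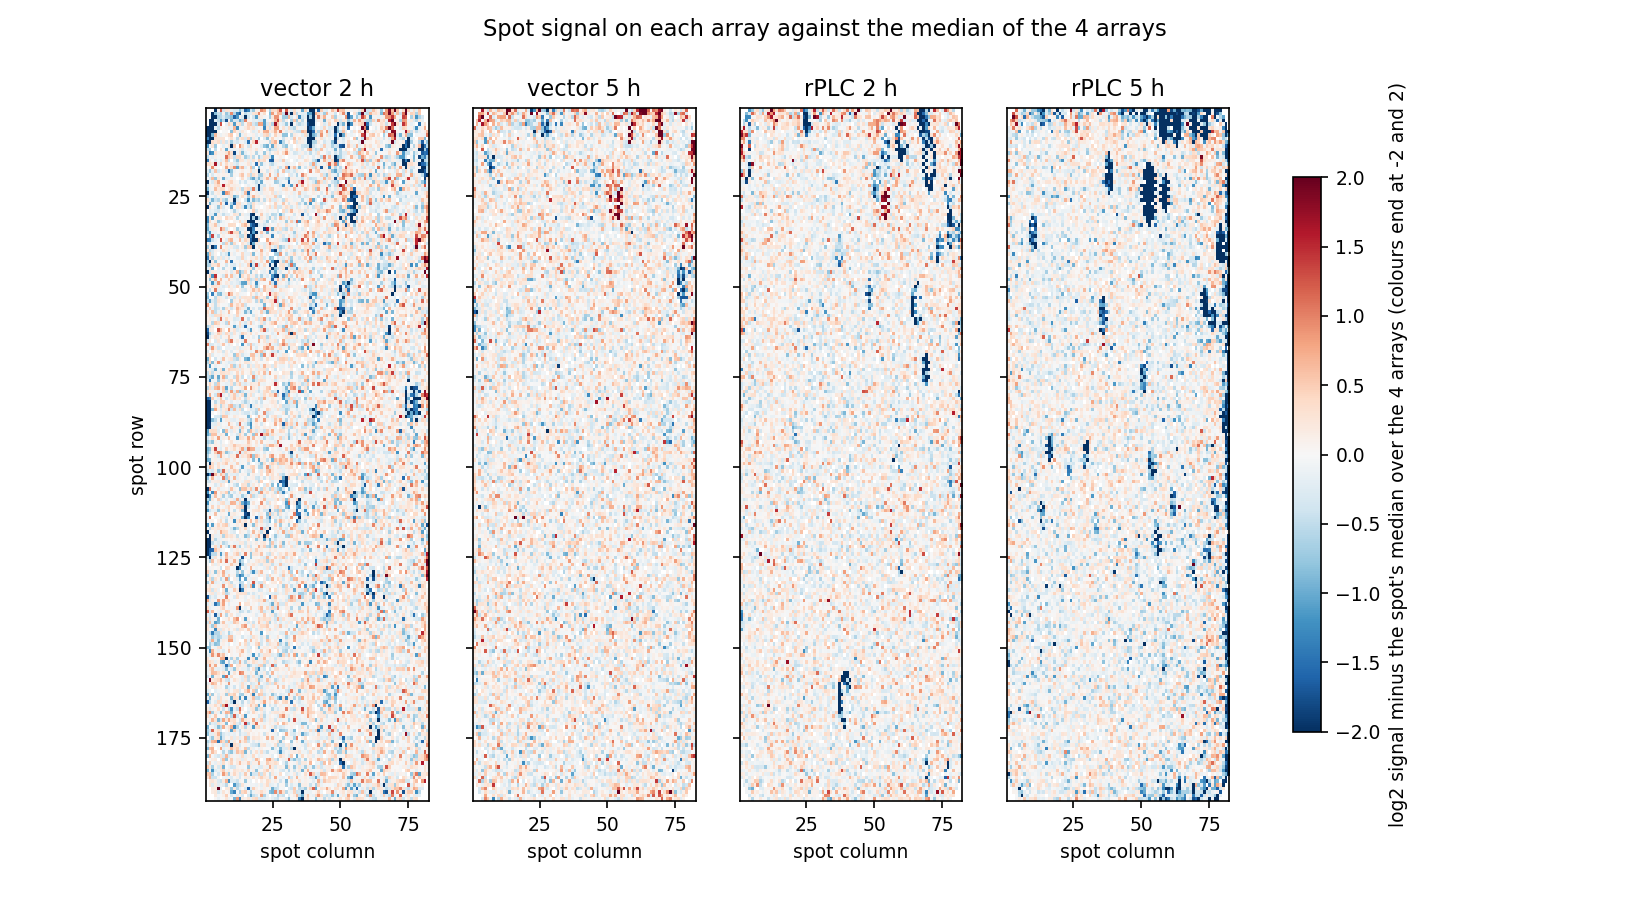
Each panel shows the spots of 1 array by array row and column, coloured by log2 signal minus the median of that spot over the 4 arrays, with colours ending at -2 and 2. Dark blue patches are largest on the rPLC 5 h array, where 5.16% of the spots lay in a dim patch, and rarest on vector 5 h, where 0.171% did.

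The markers of the strain and the plasmid were read first. HIS3, LEU2 and MET17, the amino acid synthesis genes that BY4741 lacks, were not well above background on any of the 4 arrays. URA3, the selection marker carried by pYES2, was well above background on every array. It lay higher in rPLC cells by 1.73 on the log2 scale at 2 h and 1.53 at 5 h (mean 1.63, SE 0.24, limma adjusted p = 0.583). Since the plasmid carries URA3, its fold cannot be read as a response of the yeast's own genes. The galactose genes were close to the top of the scale. GAL7, which encodes galactose-1-phosphate uridylyltransferase, was saturated on all 4 arrays, and GAL1, which encodes galactokinase, had saturated spots on every array and unflagged ones on rPLC 2 h alone, so neither has a fold. GAL10, which encodes UDP-galactose epimerase, differed by -0.48 between rPLC and vector at 2 h and was saturated on both arrays at 5 h. GAL2, the galactose permease, was saturated on every array but rPLC 2 h. PLC1, the yeast's own phospholipase C gene, had log2 folds of 0.11 at 2 h and -0.93 at 5 h, and with the dim-patch spot of its probe left out its mean was 0.08 in place of -0.41. No probe was identified for the rPLC transcript itself, which was not analysed here.

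The genes named first are those at least 2-fold apart in the same direction at both times. Across both times rPLC cells had lower SLZ1, a component of the meiotic RNA methylation complex, with log2 folds of -3.02 at 2 h and -2.80 at 5 h (mean -2.91, SE 0.24). The open reading frame YPL044C had folds of -2.85 and -2.79 (mean -2.82, SE 0.23). SND1, which acts in targeting proteins to the endoplasmic reticulum, had the lowest mean, -5.41 (SE 0.24, limma adjusted p = 0.281), with folds of -5.26 and -5.56. On the higher side stood FMP48 (3.08 and 1.52), YDL218W (2.53 and 1.93), the ferric and cupric reductase gene FRE7 (3.05 and 1.34), the pheromone-regulated PRM2 (1.92 and 1.96) and the sporulation gene SPS2 (2.01 and 1.84). The putative transporter gene PUL3 (1.85 and 1.70), the cell wall gene NCA3 (1.63 and 1.57) and PCL1, a cyclin of the Pho85 kinase (2.00 and 1.16), followed. YPR002C-A (2.49 and 1.07), YLR419W (1.13 and 2.13), the plasmid marker URA3 and the spore wall gene SPS100 completed the 12 highest. The spots of FMP48 and YLR419W lay over 2-fold apart on some array, and NCA3 had fewer than 2 spots outside dim patches on some array. FRE7 had a dim-patch spot on the rPLC 5 h array, where its spots lay 2.48 log2 units apart. Without that spot its mean was 2.57 in place of 2.20. SPS100 was saturated on the rPLC 5 h array, where it was at least 2.09-fold higher. The other 9 of the 12 lowest were RPO41, the mitochondrial RNA polymerase (mean -4.81), MCY1 (-3.95), YIP5 (-3.73), the phosphoinositide-binding HSV2 (-3.50), the Paf1 complex gene RTF1 (-3.02), TAE1 (-2.90), YDR433W (-2.82), the nitrogen regulator DAL80 (-2.63) and the sterol methyltransferase ERG6 (-2.60). The spots of these 9 and of SND1 were over 2-fold apart, in a dim patch or fewer than 2 on some array, whereas SLZ1 and YPL044C had at least 2 spots within 2-fold on every array.

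None of these 24 genes passed the test, with limma adjusted p from 0.281 to 0.632. Of 6113 genes 0 were called higher and 0 lower in rPLC cells by limma, while 133 were higher and 321 lower at an unadjusted p under 0.05. At that threshold quantile normalization gave 199 higher and 282 lower, so the size of the excess of lower genes depended on the scaling. Quantile normalization called SND1 lower (adjusted p = 0.038). Among the 4457 genes whose spots lay within 2-fold, a setting chosen after seeing the data, 4 were called lower: SLZ1 and YPL044C (both adjusted p = 0.0365), and YIR042C and GND1 (both 0.0486). With quantile normalization added to that setting, 21 genes were called higher and 30 lower.

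**Figure D2:**
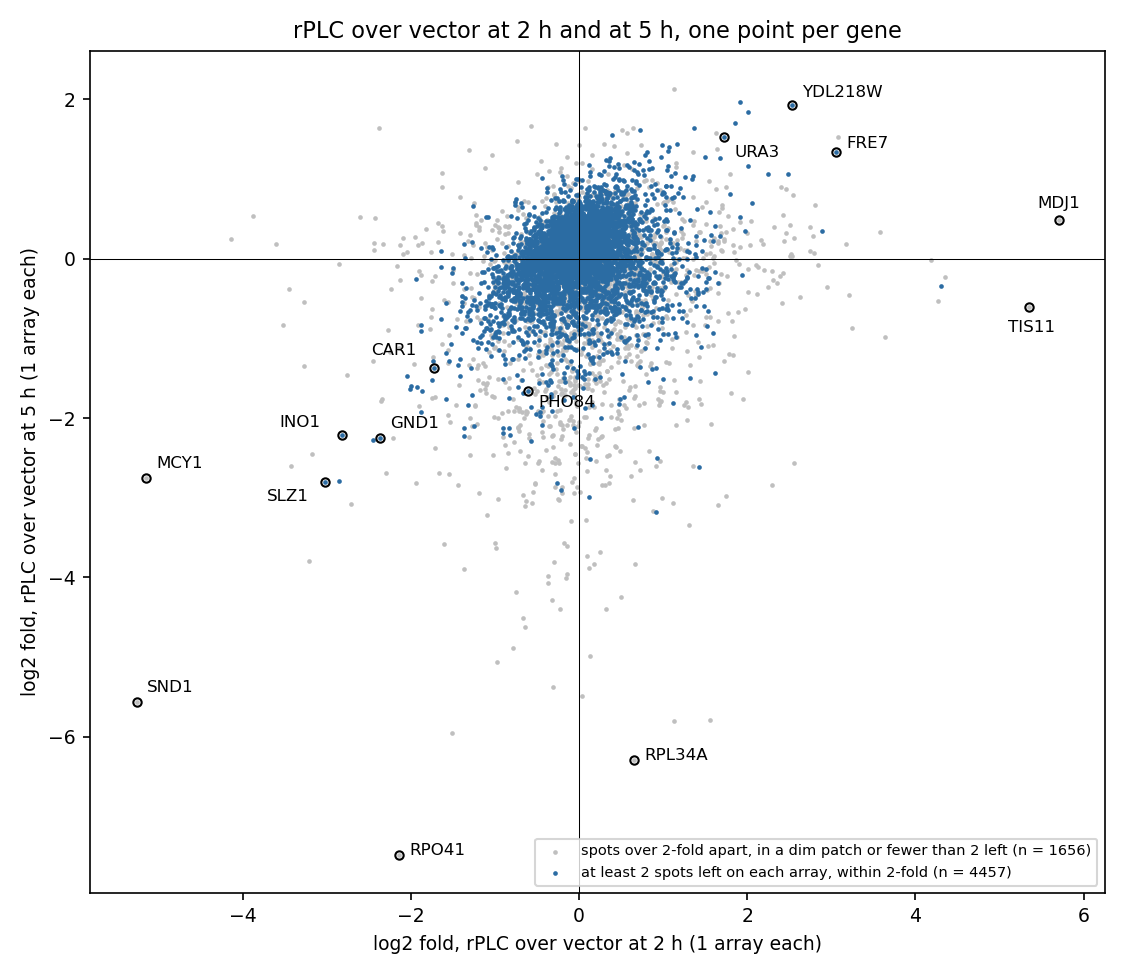
Each point is 1 of 6113 genes, with its log2 fold of rPLC over vector at 2 h on the horizontal axis and at 5 h on the vertical axis, from 1 array per group. Blue points are the 4457 genes with at least 2 spots within 2-fold on every array once dim-patch spots were left out. The plotted folds still include those dim-patch spots. Grey points are the other 1656, and RPO41, SND1, RPL34A, MDJ1 and TIS11, which lie farthest out, are grey.

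Genes of phospholipid synthesis under inositol and choline control were lower in rPLC cells as a group. INO1, which encodes inositol-3-phosphate synthase, the first step of inositol synthesis, had log2 folds of -2.82 at 2 h and -2.21 at 5 h (mean -2.52, SE 0.28, limma adjusted p = 0.583). Its spots lay within 0.178 log2 units of each other on every array. The choline transporter HNM1 followed with -1.01 and -1.74, the cholinephosphotransferase CPT1 with -0.59 and -1.21, the inositol transporter ITR1 with -0.75 and -0.55, and the phosphatidylserine synthase CHO1 with -0.73 and -0.50. The phosphatidylserine decarboxylase PSD1 had -1.37 at 2 h and 0.05 at 5 h. Of the 18 members tested 12 were lower at both times and 2 higher at both, and the list's median was -0.60 at 2 h and -0.22 at 5 h, which quantile normalization moved to -0.082. It was called lower by camera (adjusted p = 0.00379, but adjusted p = 0.759 with an estimated correlation). By limma 0 members passed over all genes and 1, INO1, passed adjusted over the list alone. At 2 h 0% of the random lists had a lower median, and at 5 h 5.35% did. The spots of HNM1, CPT1, PSD1 and ITR1 were over 2-fold apart or in a dim patch on some array.

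**Figure D3:**
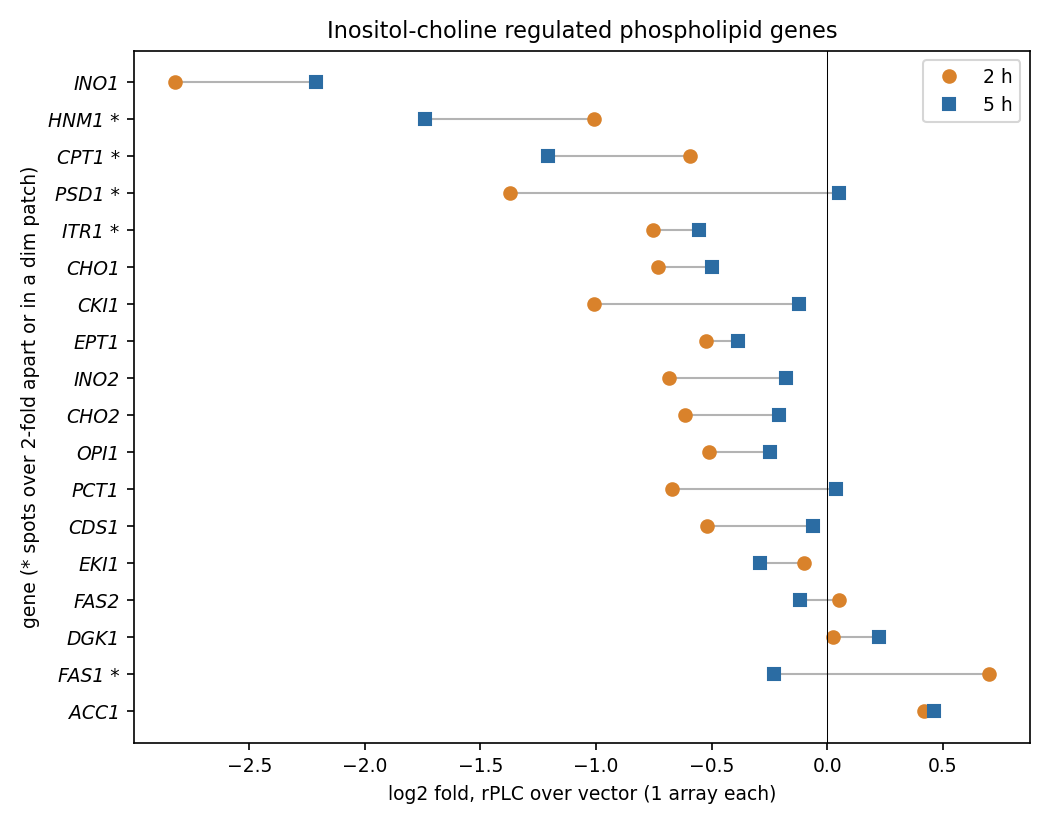
Each line is 1 of the 18 tested genes of the inositol and choline regulated phospholipid list, with the log2 fold of rPLC over vector at 2 h (circle) and 5 h (square) on the horizontal axis, 1 array per group. INO1 lies farthest left at both times, at -2.82 and -2.21, and 12 of the 18 genes lie left of 0 at both times; a star marks genes whose spots disagreed or lay in a dim patch.

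Several nutrient regulons were also lower in rPLC cells. The zinc regulon of the activator Zap1 had medians of -0.77 at 2 h and -0.94 at 5 h, and its members included the zinc transporter genes ZRT1 (mean -0.98) and ZRT2 (-1.50), ZPS1 (-1.34) and the alcohol dehydrogenase gene ADH4 (-0.92). It was called lower by camera (adjusted p = 0.00181, and adjusted p = 0.759 with an estimated correlation). Sulfate assimilation and methionine synthesis, with MET32 (-2.23), MMP1 (-1.73), MET3 (-1.54) and CYS3 (-1.42), had medians of -0.55 and -0.51 and 16 of 26 members lower at both times (camera adjusted p = 0.00016, and adjusted p = 0.759 with an estimated correlation). The phosphate regulon, with SPL2 (-1.75), the phosphate transporter PHO84 (-1.13), PHM8 (-1.10) and KCS1 (-0.91), had medians of -0.40 and -0.43 and 12 of 18 members lower at both times (camera adjusted p = 0.00598, and adjusted p = 0.759 with an estimated correlation). Arginine metabolism under the ArgR-Mcm1 regulators, with ARG3 (-1.76), CAR1 (-1.55), ARG1 (-0.997) and ARG80 (-0.43), had medians of -0.45 and -0.29 (camera adjusted p = 0.0129, and adjusted p = 0.759 with an estimated correlation). CAR1 encodes arginase, a catabolic enzyme, while ARG1 and ARG3 act in synthesis. The iron regulon had medians of -0.37 and -0.32, with HMX1 (-1.36), FRE5 (-1.32) and SIT1 (-1.06) lower and TIS11 higher at 2 h alone (camera adjusted p = 0.0176, and adjusted p = 0.759 with an estimated correlation). Nucleotide synthesis had medians of -0.23 and -0.21, with ADE17 (-1.39), URA1 (-1.05) and IMD2 (-0.99) below 0 and URA2 above (0.97, but -0.18 without the vector 2 h array) (camera adjusted p = 0.0434, and adjusted p = 0.759 with an estimated correlation), and the median of spots ended its call (adjusted p = 0.135). Of the genes named here ZRT2, ADH4, MET32, MMP1, MET3, SPL2, KCS1, ARG1, FRE5, SIT1, TIS11 and URA2 had spots over 2-fold apart, in a dim patch or fewer than 2 on some array.

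A further 3 lists, those of histones, peroxisomal fatty acid oxidation and the calcineurin-Crz1 calcium response, were lower too. The 10 histone genes had medians of -0.34 at 2 h and -0.79 at 5 h, with 8 lower at both times. The 7 whose spots lay within 2-fold had medians of -0.066 and -0.884, with 5 lower at both times. Their largest means were HHF2 (-2.31) and HTA2 (-1.54), whose spots disagreed, and HTB2 (-0.84), whose spots did not, and HHF1 was saturated on the vector 2 h array. Camera called the list (adjusted p = 0.0122, and adjusted p = 0.759 with an estimated correlation). Fatty acid oxidation had medians of -0.55 and -0.30, with FAA2 (-0.93), TES1 (-0.72) and PEX11 (-0.71), and ECI1, saturated on the vector 2 h array, was at least 2.11-fold lower at 2 h and 2.06-fold lower at 5 h (camera adjusted p = 0.0129, and adjusted p = 0.759 with an estimated correlation). The calcineurin list had medians of -0.32 and -0.22, with PUN1 (-1.83), MEP1 (-1.52, and -0.814 without its dim-patch spot) and the sodium pump genes ENA1 and ENA2 (both -0.86) (camera adjusted p = 0.0229, and adjusted p = 0.759 with an estimated correlation). ENA1 had spots over 2-fold apart, in a dim patch or fewer than 2 on some array. Under quantile normalization the medians at 5 h were -0.556 for the zinc list, -0.345 for sulfur, -0.282 for phosphate, -0.145 for arginine, -0.089 for iron, -0.201 for nucleotides, -0.692 for histones, -0.122 for fatty acid oxidation and -0.106 for calcineurin. By limma 0 members of any of these 9 lists passed over all genes. Adjusted over the list alone, 4 passed in the zinc list, 3 in the sulfur list, 2 in the arginine list, 1 each in the phosphate and calcineurin lists and 0 in the iron, nucleotide, histone and fatty acid lists.

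Respiratory, G1/S and meiotic genes were higher in rPLC cells as groups. The tricarboxylic acid cycle and respiratory chain list had medians of 0.36 at 2 h and 0.45 at 5 h, with 22 of 42 members higher at both times and 4 lower at both (camera adjusted p = 6.18e-05, and adjusted p = 0.759 with an estimated correlation). The ATP synthase gene ATP3, with 1 saturated spot on the rPLC 2 h array, was at least 1.73-fold higher at 2 h. At 5 h it had a log2 fold of 1.30. The members with larger means did not move together: KGD1 had 3.64 at 2 h and -0.98 at 5 h, LSC2 had -1.12 and -1.64 (mean 0.418 by the median of spots), and SDH1, saturated on the vector 2 h array, was at least 2.29-fold lower at 2 h and had -1.52 at 5 h. The spots of all of them disagreed. Under quantile normalization the list's median at 2 h was 0.064 in place of 0.359. Of the 24 genes for G1/S cyclins and DNA replication 14 were higher at both times and 3 lower at both, with medians of 0.26 and 0.28 (camera adjusted p = 0.00379, and adjusted p = 0.759 with an estimated correlation). PCL1 (mean 1.58), the G1 cyclins CLN1 (1.39) and CLN2 (0.62) and the Cdc28 inhibitory kinase SWE1 (0.69) led it. The meiosis and sporulation list, defined as genes that are off in mitotic haploids such as BY4741, had medians of 0.42 and 0.12. Of its 20 members 11 were higher at both times and 4 lower at both. Its call does not show that a meiotic programme was active, and the meiotic gene SLZ1 named above was lower at both times. SPS2 (mean 1.92), DIT2 (1.39), SPR3 (1.20) and SPO22 (0.88) led it (camera adjusted p = 0.0233, and adjusted p = 0.759 with an estimated correlation), and leaving out dim patches ended its call (adjusted p = 0.0764). Under quantile normalization the medians at 5 h were 0.554 for the respiratory, 0.497 for the G1/S and 0.545 for the meiosis list. SWE1 and DIT2 had spots over 2-fold apart, in a dim patch or fewer than 2 on some array. By limma 0 members of these 3 lists passed over all genes, and adjusted over the list alone 1 passed in the meiosis list and 0 in the others.

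The 137 cytosolic ribosomal protein genes differed between the times. Their median was 1.097 in rPLC over vector at 2 h and -0.31 at 5 h, above all and below all of the random lists respectively. Camera, which averages the times, called the list higher (adjusted p = 6.18e-05, and adjusted p = 0.943 with an estimated correlation). The members with the largest means were RPL34A (-2.82), RPS7B (-2.46), RPL42B (-2.31) and RPS16A (1.98), each with a dim-patch spot, and the first 3 lay against the list's direction. Without the rPLC 5 h array the mean of RPL34A was 0.41, and without the vector 2 h array that of RPS16A was -0.05. By limma 0 members passed over all genes and 0 adjusted over the list alone. Ribosome biogenesis had medians of 0.72 at 2 h and -0.48 at 5 h and was not called (camera adjusted p = 0.399), with NSR1, DBP2, RPA49 and RLP7 at means of -0.97, -0.93, -0.79 and -0.73. Without their dim-patch spots NSR1 had 0.028, RPA49 0.119 and RLP7 -0.234, and the spots of DBP2 disagreed too. Glycolysis and hexose transport had medians of 0.53 and -0.36, or 0.224 and -0.082 under quantile normalization, and was not called (camera adjusted p = 0.836). In it the hexokinase gene HXK2 had -1.37 at 2 h and -2.12 at 5 h, and the transporter gene HXT2 had -1.20 and -1.12. The low-affinity transporter gene HXT3 had 1.36 and 1.64, and the pyruvate decarboxylase gene PDC5 -1.005 and -0.55. Translation factors had medians of 0.46 and -0.19 (camera adjusted p = 0.41).

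**Figure D4:**
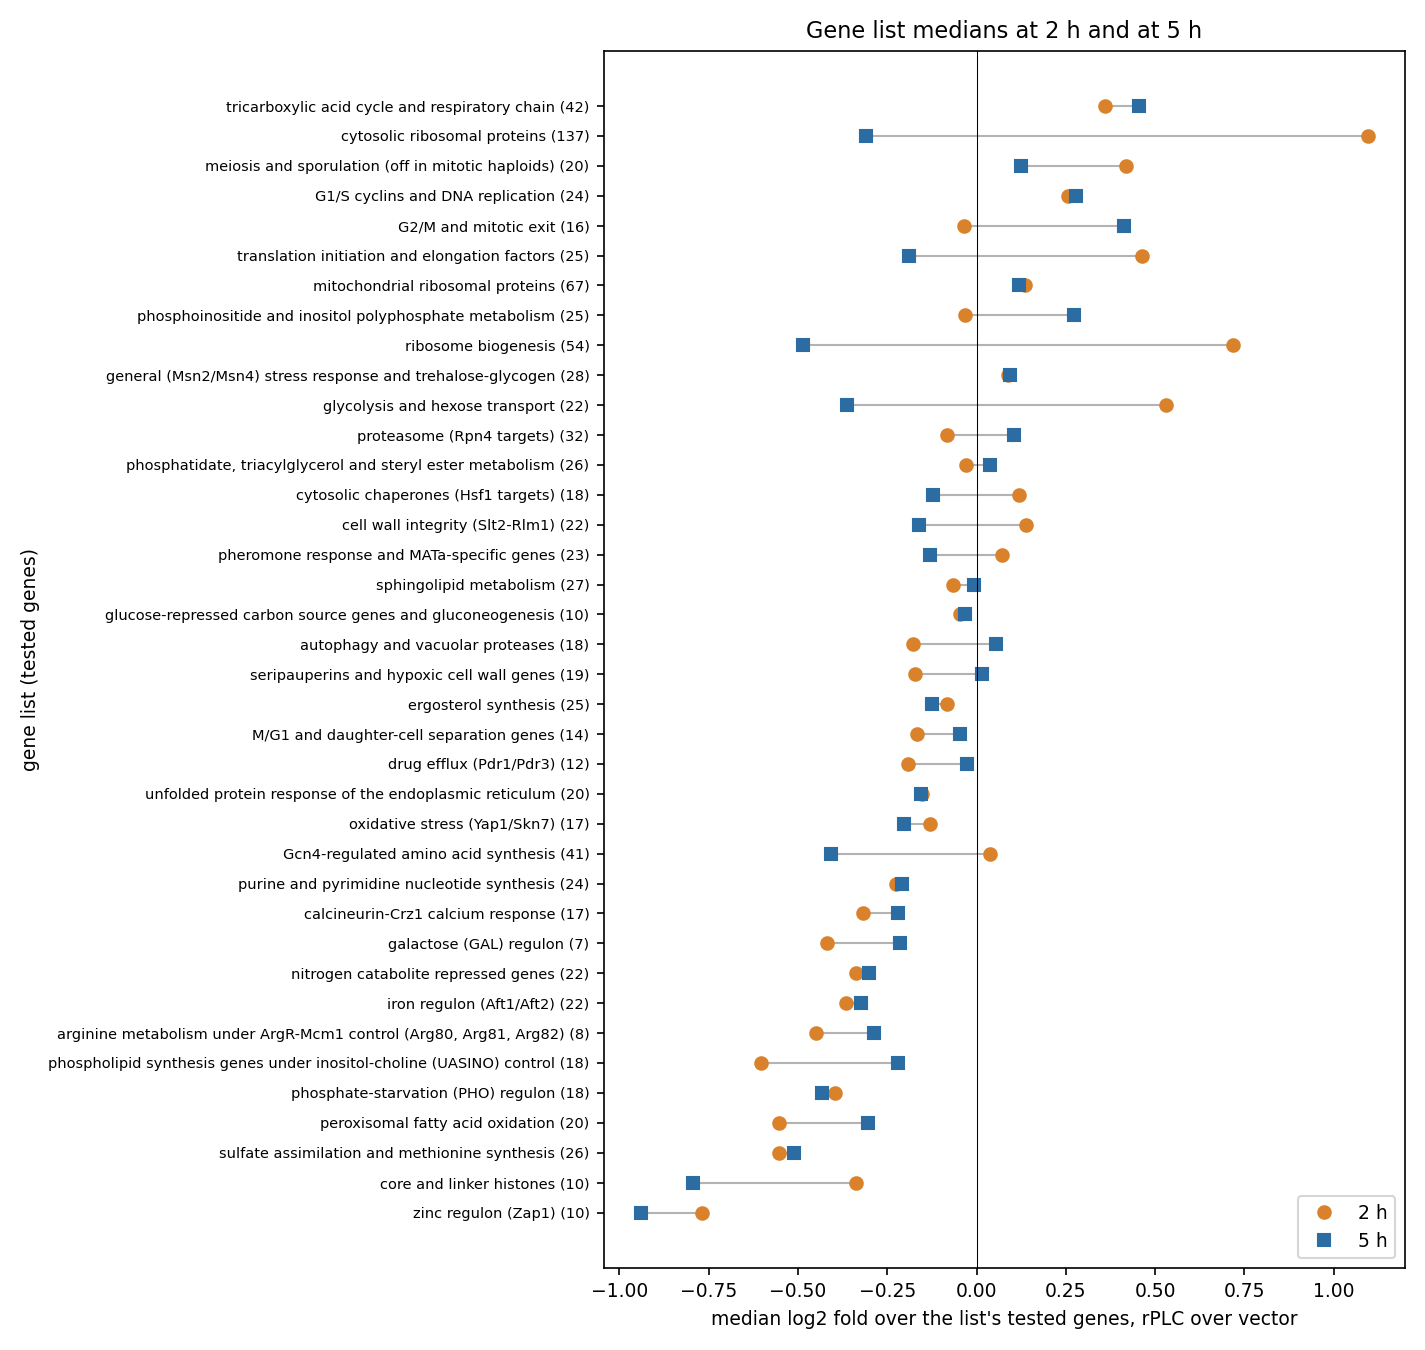
Each line is 1 gene list with its number of tested genes, with the median log2 fold of rPLC over vector at 2 h (circle) and at 5 h (square) on the horizontal axis, 1 array per group. The zinc list lies lowest, at -0.77 and -0.94, and the cytosolic ribosomal protein list spans 1.097 at 2 h to -0.31 at 5 h.

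The other lists were not called by camera, and their medians at 2 h and 5 h are given in that order. Among lipid lists, phosphatidate and triacylglycerol metabolism had -0.03 and 0.04 (adjusted p = 0.903), phosphoinositides -0.03 and 0.27 (0.506), sphingolipids -0.06 and -0.01 (0.316) and ergosterol synthesis -0.08 and -0.12 (0.199). The galactose genes had -0.42 and -0.21 (0.222), glucose-repressed genes -0.05 and -0.03 (0.897), Gcn4-regulated amino acid synthesis 0.04 and -0.41 (0.0695) and nitrogen catabolite repressed genes -0.34 and -0.30 (0.097). Of the stress lists, the general response had 0.09 and 0.09 (0.333), chaperones 0.12 and -0.12 (0.941), the unfolded protein response -0.15 and -0.16 (0.268), oxidative stress -0.13 and -0.20 (0.399), cell wall integrity 0.14 and -0.16 (0.47), drug efflux -0.19 and -0.03 (0.709) and the pheromone response 0.07 and -0.13 (0.841). The G2/M list had -0.04 and 0.41 (0.247), the daughter-cell list -0.17 and -0.05 (0.533), autophagy -0.18 and 0.06 (0.841), the proteasome -0.08 and 0.11 (0.841), hypoxic cell wall genes -0.17 and 0.01 (0.782) and mitochondrial ribosomal proteins 0.14 and 0.12 (0.0695). By limma 0 members of these lists passed over all genes. Adjusted over the list alone, 2 passed in the drug efflux list and 1 each in the Gcn4 and pheromone lists, and 0 in the others. Quantile normalization called the Gcn4 list (adjusted p = 0.014) and the nitrogen list (0.031) lower, and it turned the median of the general stress list at 2 h to -0.22. The mean and camera's direction differed in sign for the phosphoinositide, glycolysis, chaperone, pheromone, translation factor, G2/M, autophagy and proteasome lists, and between the times for the translation factor and nucleotide lists.

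At 2 h alone 361 of 6145 genes were at least 2-fold higher in rPLC cells and 279 at least 2-fold lower. The highest were MDJ1, a mitochondrial chaperone (5.70), TIS11, an iron-responsive RNA-binding protein (5.35), CSS2, which was at least 20.3-fold higher, the ribosomal protein gene RPS16A (4.30) and the acetyl-CoA synthetase gene ACS1 (4.27). SND1 (-5.26), MCY1 (-5.15), the protein kinase A subunit TPK3 (-4.14), the NADH dehydrogenase gene NDE2 (-3.88) and PPQ1 (-3.61) were lowest. The spots of all 10 genes disagreed, lay in dim patches or were fewer than 2 on some array. With its dim-patch spot on vector 2 h left out the mean of RPS16A over both times was 0.514 in place of 1.978. At 5 h 100 of 6115 genes were at least 2-fold higher and 638 lower. YLR419W (2.13), PRM2 (1.96), YDL218W (1.93), SPS2 (1.84) and PUL3 (1.70) were highest. RPO41 (-7.48), the ribosomal protein gene RPL34A (-6.29), YIP5 (-5.95), the lipid droplet seipin gene SEI1 (at least 55.9-fold lower) and PUS6 (at least 50-fold lower) were lowest, and the spots of all these lowest genes disagreed, lay in dim patches or were fewer than 2. Of the genes at least 2-fold lower at 5 h 81.7% had a dim-patch spot or spots over 2-fold apart on an array of that time, against 21.1% of all genes. Quantile normalization gave 201 higher and 491 lower at 5 h, and among genes whose spots lay within 2-fold 39 were higher and 150 lower.

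The direction was shared between the times for 29 genes at least 2-fold higher at both and 102 at least 2-fold lower at both. In opposite directions, 42 genes were at least 2-fold higher at 2 h and lower at 5 h, and 5 the reverse. Across genes, which are not independent replicates, the folds at 2 h and 5 h correlated with Pearson's r of 0.197 and Spearman's rho of 0.214. Under quantile normalization 44 genes were higher and 89 lower at both times, and the median fold of all genes at 5 h moved from -0.03 to 0.12. With normexp background correction 19 genes were higher at both times, and among genes whose spots lay within 2-fold 15 were higher and 37 lower at both. Among these 4457 genes 7 were at least 2-fold higher at 2 h and lower at 5 h, 0 the reverse, and Pearson's r was 0.349. With quantile normalization added 28 were at least 2-fold higher and 32 lower at both times.

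Between 2 h and 5 h of induction, the lists of respiration and fatty acid oxidation had medians below 0 with both plasmids. Camera called both lists at the preset correlation but neither with an estimated one (camera adjusted p = 0.896 for each). The genes named first are those at least 2-fold apart in the same direction with both plasmids. Among them BBC1, which acts in actin patch assembly, had the lowest mean fold of 5 h over 2 h, -2.51 (SE 0.23), with -2.49 in vector and -2.53 in rPLC cells and spots within 2-fold. The next lowest means were the nuclear pore gene POM33 (-2.41), TAF13 (-2.39), the pyruvate dehydrogenase subunit PDX1 (-2.35), YAP1802 (-2.32), the proline permease PUT4 (-2.19), YPP1 (-2.16), YBL100C (-2.05) and the potassium transporter TRK2 (-1.96). The cell wall mannoprotein gene TIR1 (-2.31), saturated on both 2 h arrays, and SDH1 (-2.08) and ATP1 (-1.955), saturated on vector 2 h, were among the 12 lowest too. The spots of these 3 also lay over 2-fold apart at 5 h, so their means are neither exact folds nor bounds. The highest means among them were the glycogenin gene GLG1 (2.99), the vacuolar iron transporter CCC1 (2.497), SNU13 (2.49), ESF2 (2.14), TMA23 (1.97), MED6 (1.96), IMD3 (1.72), the sterol genes ERG5 (1.67) and ERG25 (1.41), DPH6 (1.51), OGG1 (1.44) and RPL12A (1.37). Of these 24 genes BBC1, ERG5 and ERG25 had at least 2 spots within 2-fold on every array and none in a dim patch. With its dim-patch spot on rPLC 5 h left out PUT4 had a mean of -1.075 in place of -2.186. Their limma adjusted p was 0.56 throughout, and of 6113 genes 0 were called higher and 0 lower, with 176 higher and 341 lower at an unadjusted p under 0.05.

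Camera called 8 lists between the times. The respiratory list was lower, with medians of -0.66 in vector and -0.49 in rPLC cells and 37 of 42 members lower in both, among them CYT1 (mean -1.26, and -0.777 without its dim-patch spot) and ATP4 (-1.73) (camera adjusted p = 1.41e-10, and adjusted p = 0.896 with an estimated correlation). Peroxisomal fatty acid oxidation had medians of -0.49 and -0.36 and 11 of 20 members lower in both, with TES1 (-0.93), POX1 (-0.72), FAA2 (-0.67) and CAT2, which was saturated on the vector 2 h array (camera adjusted p = 0.00747, and adjusted p = 0.896 with an estimated correlation). Glucose-repressed genes had medians of -0.49 and -0.72, with MDH2 (-1.01) and the lactate permease JEN1, saturated on both 2 h arrays, lower and ACS1 at 3.918 in vector but -0.884 in rPLC cells, and MLS1 was saturated on the vector 2 h array (camera adjusted p = 0.00921, and adjusted p = 0.896 with an estimated correlation). Hypoxic cell wall genes had -0.44 and -0.17, with TIR2 (-1.30) and PAU5 (-0.94) lower and ANB1 higher (2.51) (camera adjusted p = 0.0158, and adjusted p = 0.896 with an estimated correlation). The galactose genes, with GAL3 (0.44) and PGM2 (0.45), had medians of 0.46 and 0.45, in part from saturated spots in 4 of the 7 members (camera adjusted p = 0.02, and adjusted p = 0.896 with an estimated correlation). The G1/S list, with SMC3 (1.13), MCD1 (1.09) and CDC21 (0.81) higher and CDC9 at -0.88 (0.33 with dim patches left out), had medians of 0.28 and 0.42 (camera adjusted p = 0.000254, and adjusted p = 0.896 with an estimated correlation). Ribosome biogenesis, with NOP56 (1.25), IMP4 (1.04, and 0.309 without its dim-patch spot), ERB1 (0.995) and UTP9 (0.99), had medians of 1.08 in vector and 0.00 in rPLC cells (camera adjusted p = 2.92e-07, and adjusted p = 0.898 with an estimated correlation). Cytosolic ribosomal proteins, with RPS16A (1.74, and 0.286 without its dim-patch spot), RPS20 (1.23) and RPL34A (-2.99), each with opposite signs in vector and rPLC cells, had medians of 1.21 and -0.25 (camera adjusted p = 5.37e-09, and adjusted p = 0.898 with an estimated correlation). Of the 137 ribosomal protein genes 40 were higher with both plasmids, RPL12A among them, and 0 were lower with both. By limma 0 members of these lists passed over all genes, and adjusted over the list alone 1 passed in the hypoxic list and 0 in the others. The other 30 lists had camera adjusted p from 0.111 to 0.97, and among them 4 genes of the iron list passed adjusted over the list alone. Of the genes named here ATP4, CAT2, ACS1, PAU5, ANB1, SMC3, CDC9, ERB1, UTP9, RPS20 and RPL34A had spots over 2-fold apart, in a dim patch or fewer than 2 on some array. Under quantile normalization the medians in rPLC cells were -0.322 for respiration, -0.136 for fatty acid oxidation, -0.374 for glucose-repressed genes, -0.041 for the hypoxic list, 0.137 for ribosome biogenesis and -0.108 for ribosomal proteins, and the galactose list had 0.219 in vector cells. Quantile normalization ended the call of the galactose list (adjusted p = 0.0658), and with spots within 2-fold the hypoxic list was not called (0.0564).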

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

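Every value in this part was singled out for the same reason: the effect of the plasmid pointed in opposite directions at the 2 times, or the effect of time in opposite directions in cells with the 2 plasmids. For lists this means a median outside the middle 95% of random lists on opposite sides, and for genes a fold of at least 2 in opposite directions. With 1 array per group none of these differences could be tested. Of the tests in this part, those on quantile normalization alone, on spots that lie within 2-fold, without dim patches or by their median, and on the vector 2 h array were chosen after the result was seen.

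Among lists, glycolysis and hexose transport had a median of 0.53 in rPLC over vector at 2 h and -0.36 at 5 h, or 0.224 and -0.082 under quantile normalization, and ribosome biogenesis 0.72 and -0.48. Cytosolic ribosomal proteins had 1.097 and -0.31, and from 2 h to 5 h their median was 1.21 in vector and -0.25 in rPLC cells. Among genes, the folds of rPLC over vector at 2 h and 5 h were 1.13 and -5.80 for SEI1, 1.55 and -5.78 for PUS6, 1.12 and -3.07 for NSR1, and 1.80 and -1.68 for the hypoxic translation factor gene ANB1. From 2 h to 5 h in vector and in rPLC cells, RPO41 had 2.30 and -3.04, SEI1 1.39 and -5.54, PUS6 1.97 and -5.37, and KGD1 2.64 and -1.98. RPL42B had 1.25 and -2.92, NSR1 2.89 and -1.30, and RPA49 1.58 and -1.84. The spots of each of these genes were over 2-fold apart or in a dim patch on some array. SEI1 and PUS6 were not well above background on the rPLC 5 h array, so their folds against it are not exact and stand only as at least 55.9-fold and 50-fold lower in rPLC cells at 5 h.

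The ribosomal protein genes stood out on the vector 2 h array, where their median log2 level was -0.18, against 1.13 on vector 5 h, 0.94 on rPLC 2 h and 0.62 on rPLC 5 h. Saturation of bright spots is argued against, since the 128 of 137 genes without a saturated spot had a median of 1.03 at 2 h. Dim patches and spots over 2-fold apart are argued against too, since members whose spots lay within 2-fold had a median of 1.11. What stays open for the fold at 2 h is whether the vector 2 h culture or array alone differed. Its level lay 0.796 below the lowest of the other 3, which spanned 0.512. With 1 array this cannot be told apart from an effect of rPLC that differs with time. The fold at 5 h does not use that array, so that array alone could not account for the median of -0.31 there. Ribosome biogenesis genes had median levels of -2.93 on vector 2 h, -1.67 on vector 5 h, -2.29 on rPLC 2 h and -2.21 on rPLC 5 h. An early growth-related response of the vector cells or of the rPLC cells may lie behind the fold of the ribosomal protein genes at 2 h, and neither was tested.

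The count of genes at least 2-fold lower at 5 h in rPLC cells, 638, was the largest of the per-time counts. Spot defects can account for a part of the number: among genes whose spots lay within 2-fold 3.37% were at least 2-fold lower, against 10.4% of all genes. Leaving out dim patches alone left 396 genes and the median of spots 509, and the filter on spots also lowered the counts at 2 h, from 361 to 144 higher and from 279 to 111 lower. The excess of lower over higher genes was 6.38 to 1 over all genes. It was 3.85 in genes with such spots and 2.44 under quantile normalization of all genes, so neither setting alone removed it. The filter on spots may leave milder defects in place, so it cannot exclude defects alone as the cause. With both settings together the excess was 0.973, so it may come from defects and scaling combined. However, quantile normalization gives every array the same distribution and so favours a balance. A true broad fall in transcripts at 5 h was not tested apart from these.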

How the results depend on the processing

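The alternatives named with dim patches, with spots within 2-fold or with the median of spots were chosen after seeing the data; all others were fixed in advance. The causes of the differences were not tested, except where a setting removes genes or lowers a threshold by construction.

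Of the counts of genes and lists, 131 stayed within 1.5 times the reported value and 29 moved further. Genes called lower in rPLC cells numbered 1 under quantile normalization and 4 with spots within 2-fold, against 0. With both together 21 were called higher and 30 lower, and 4 were called lower at 5 h than at 2 h, limma's prior resting on 7.70 degrees of freedom in place of 2.69. The other settings, an adjusted p under 0.1 and each array left out in turn (from 0 to 0 genes) included, called 0 genes in either contrast. With spots within 2-fold the genes at least 2-fold higher and lower numbered 144 and 111 at 2 h, 39 and 150 at 5 h, and 15 and 37 at both times, among 4457 genes. With quantile normalization added they numbered 132 and 122 at 2 h, 74 and 72 at 5 h, and 28 and 32 at both times. Leaving out dim patches alone gave 396 lower at 5 h. Quantile normalization gave 201 higher at 5 h and 44 higher at both times, and normexp gave 19 higher at both times. A 1.5-fold threshold gave 881 and 786 at 2 h, 477 and 1158 at 5 h, and 131 and 316 at both times.

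The 14 lists called by camera between the plasmids were kept under every other normalization, background, filter and block run on lists, except that leaving out dim patches lost the meiosis list and the median of spots the nucleotide list, each keeping 13. Of the 8 lists called between the times, quantile normalization and spots within 2-fold each kept 7 and both together 6. Lists that an alternative called and the reported setting did not were the Gcn4, nitrogen, oxidative stress, galactose and mitochondrial ribosomal lists between the plasmids and the ergosterol, iron and proteasome lists between the times. An estimated correlation called 0 lists in either contrast. Directional fry called 0 between the plasmids (adjusted p from 0.213 to 0.997) and 1 between the times, meiosis and sporulation (adjusted p = 0.0101).

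Of the mean folds of named genes, 2244 values kept their direction and their side of the threshold, 28 passed it under an alternative and 26 turned direction. Between the plasmids, the median of spots gave LSC2 0.42, RPA49 0.10 and PLC1 0.048. Leaving out dim patches gave NSR1 0.028, RPA49 0.12 and PLC1 0.078, and CDC9 0.33 between the times. With spots within 2-fold RPA49 had 0.12 and PLC1 0.078, and with quantile normalization added 0.19 and 0.10. With each array left out in turn and no block, the means between the plasmids ran from -0.18 to 2.13 for URA2, -0.82 to 5.56 for TIS11, -6.05 to 0.41 for RPL34A and -0.054 to 4.01 for RPS16A. They ran from -2.42 to 0.47 for NSR1, -1.71 to 0.13 for RPA49, -0.37 to 0.19 for GAL2, -0.82 to 0.11 for GAL10 and -0.84 to 0.018 for PLC1, and as GAL2 was saturated on 3 arrays and GAL10 on 2, their ranges are not folds. Between the times they ran from -1.35 to 0.011 for FAA2, -0.62 to 3.65 for ACS1, -6.13 to 0.16 for RPL34A and -0.41 to 3.89 for RPS16A. Of the folds at 1 time 135 kept their value and 26 moved by more than 1.5-fold. For INO1 between the plasmids the adjusted p ran from 0.00252 to 0.932 over the alternatives, and its mean from -2.84 to -2.19. A slide block was not run, since all arrays lay on 1 slide, and the brightest probe of a gene gave no other value, since each gene had 1 probe. The reported model pairs the arrays by time as a block, and without that block 0 genes were called and the 14 and 8 lists were kept. With 1 replicate in each group no other pairing could be formed.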

Other observations

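The settings described first in this part, and the tests on spots and on the cultures, were chosen after the results were seen; the test of the phospholipid list without INO1 at the preset correlation was set before its result, and that with an estimated correlation after it.

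Among the 4457 genes with spots within 2-fold and quantile normalization, limma called 21 genes higher and 30 lower in rPLC cells, the most of any setting run, so these calls stand as hypotheses. They included the 4 genes called with such spots alone, and SND1 was not among the genes tested. The lower genes included SLZ1 (adjusted p = 0.00207), INO1 (mean -2.53, adjusted p = 0.00252) and the pentose phosphate pathway genes GND1 (-2.40, adjusted p = 0.00252) and TKL1 (-1.38, 0.0247). They also held the hexokinase gene HXK2 (-1.77), the glutamate dehydrogenase gene GDH1 (-1.65), the amino acid permease gene AGP1 (-1.48), the arginine genes ARG3 (-1.72) and CAR1 (-1.56), CYS3 (-1.38), the purine gene ADE17 (-1.42), the aldehyde dehydrogenase gene ALD6 (-1.38) and the zinc-responsive ZPS1 (-1.35). The higher genes included FRE7 (2.74), YDL218W (2.21), SPS2 (2.05), PRM2 (2.03) and the plasmid marker URA3 (1.61). Also among them were HXT3 (1.49), the copper transporter gene CTR1 (1.43), CLN1 (1.39), PCL1 (1.60) and SPR3 (1.37). Their folds were at or beyond about 2-fold in the same direction at both times. Between the times this setting called 4 genes lower at 5 h: BBC1 (-2.45, adjusted p = 0.00927), and YAR062W (-1.75), the flocculin gene FLO9 (-1.71) and the transcription elongation factor gene SPT5 (-1.65), each with adjusted p = 0.0442. GND1, TKL1, GDH1, AGP1, ALD6, CTR1, YAR062W, FLO9 and SPT5 lie outside the naming rule and were chosen after their values were seen.

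The lower level of INO1 and its list in rPLC cells is the pattern closest to phospholipid metabolism. Spot defects are argued against for INO1 itself, since the spots of its probe lay within 0.178 log2 units on every array with 0 in a dim patch. That probe says nothing of the other members. The 13 members whose spots lay within 2-fold had medians of -0.509 at 2 h and -0.272 at 5 h (camera adjusted p = 0.00777 at the preset correlation). INO1 alone is argued against as the carrier of the list, since the other 17 members kept medians of -0.593 at 2 h and -0.208 at 5 h and an unadjusted camera p of 0.0034 at the preset correlation. With an estimated correlation their p was 0.314, and the whole list with INO1 was not called there either (adjusted p = 0.759). A difference between the cultures other than the phospholipase stays open and cannot be told apart from it with 1 array per group. Across genes the folds at 2 h and 5 h correlated with r of 0.197, or 0.349 among genes whose spots lay within 2-fold.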
